A study of Mus musculus with 3 samples.

How the data were processed

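Total RNA of whole mouse embryos, pooled from 3 embryos per sample, was amplified, labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels. There were 3 arrays, 1 in each of 3 groups: MafF-/-:MafG-/-:MafK-/- at E10.5, and MafF-/-:MafG+/+:MafK-/- at E10.5 and at E9.5. All 3 arrays lay on slide 1 and were read in scan 1, so slide and scan do not separate the groups.

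The deposited values are scanner output. Per the file headers, the authors read them with Agilent Feature Extraction 9.5.3.1 under protocol GE1-v5_95_Feb07 from array design 014868, whose annotation uses build mm7, and the tool is also named in the submitters' processing notes. The signal used is a background-subtracted intensity on a linear scale, per the file headers. The value table the authors deposited beside it holds the same intensity, rounded (largest difference 0.497%), on a linear scale with no centring between arrays; its medians were 84.0, 115 and 83.4 for triple null, MafG-intact E10.5 and MafG-intact E9.5.

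The log2 intensity of each of 43379 non-control spots (of 45018) was taken minus the 75th percentile of its array, which was 1078, 1420 and 1064 in the same order. Control spots and spots marked as outliers (59, 52 and 83) were left out; no non-control spot was saturated. Spots of a probe were averaged (245 probes were printed 10 times). Of 41174 probes, 4 were lost to outlier marks and 18220 had no single gene symbol (none, or more than 1). The other 22950 had 1 gene symbol through their RefSeq accession in a table of assembly GRCm38.p6. That assembly differs from the build of the array design, so it gave names, chromosomes and gene order and no coordinates. Probes of a gene that were well above background on at least 1 array were averaged, which gave 13184 genes, 4447 of them with several probes; of the genes at least 2-fold apart with several probes, 164 of 172, 162 of 170 and 23 of 32 had all probes on the same side in the first, the second and the third comparison.

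With 1 array per group there is no replicate check, and no p-value or standard error is given. A gene was counted when it was well above background on both arrays of a comparison and at least 2-fold apart. A gene above background on 1 array of a pair has a bound, given as "at least N-fold": its level on the bright array over the higher of its own signal and the lowest signal among probes well above background on the dim array. For 29 of 30 gene lists (the large Maf list, with 2 measured genes, was given no median), the median log2 difference over genes above background on at least 1 of the 3 arrays was placed among 10000 random lists of the same size matched on mean level in 20 bins, as a description of these arrays. The steps were tested on simulated data for the first comparison, on 12860 genes with spot noise. In it 100 of 100 genes changed 2.5-fold and 100 of 100 changed 4-fold were recovered, and 12 of 12660 unchanged genes came out 2-fold apart. The changed genes were drawn from those above background and not dim on the MafG-intact E10.5 array, so recovery of dim genes was not tested.

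Groups, comparisons, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule took, for each of the first 2 comparisons, the 10 genes highest and the 10 lowest among those above background on both arrays, at or above the median level, with probes agreeing in sign; the 5 largest bounds in each direction; for the third comparison the 5 highest and 5 lowest; the small Maf genes; from each list the members at least 2-fold apart or, if none, the 2 farthest apart; and the 10 genes farthest from both MafG-intact arrays in the triple null pool. The text prints some of the list members so chosen, and some genes the rule takes are not reported here. Symbols that are only clone or predicted-gene names were counted and not named.

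The alternatives were normexp background correction (offset 50), quantile normalization, scaling on the median of detected genes, other filters on dim probes, the brightest probe of a gene, thresholds of 3-fold and 1.5-fold, and the deposited value table. Normexp used the median spot intensity because the deposited scanner tables hold no mean spot intensity. Scaling on 10 spike-in probes and leaving out X and Y genes were added after the data were seen. Spike-in probes differed between arrays by a median of 0.02, 0.01 and 0.03 (log2, signed) after scaling in the first, the second and the third comparison. Single spike-in probes ranged from -0.05 to 0.35, from -0.34 to 0.07 and from -0.05 to 0.22 in the same order. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.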

Results

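Transcript levels were measured in whole mouse embryos that lacked 2 or 3 of the small Maf proteins, bZIP partners that CNC and BACH family transcription factors need to bind DNA. The 3 groups were embryos lacking MafF, MafG and MafK at stage E10.5 (triple null), and embryos lacking MafF and MafK with both copies of MafG, at E10.5 and a day younger, at E9.5 (MafG-intact). Each group was a single array hybridised with RNA from a pool of 3 embryos of mixed background, so no difference below has a replicate error, and none was tested. "Higher" and "lower" describe these 3 arrays. Of 41174 probes, 69.2% were well above background on the triple null array, 70.4% on the MafG-intact E10.5 array and 69.1% on the E9.5 array, and the number of arrays limits the precision. Spots of probes printed 10 times varied on the MafG-intact E10.5 array with a median SD of 0.05 (log2) at levels from 0 to 2 and of 0.26 at levels under -6, which covers printing and scanning and not the embryos.

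The targeted gene was read first. Mafg was not well above background on the triple null array and was at least 173-fold lower there than on the MafG-intact E10.5 array and at least 253-fold lower than on the E9.5 array. Between the MafG-intact arrays Mafg was 1.46-fold lower at E10.5. Maff and Mafk gave signal above background on every array although both genotypes lack both proteins, with triple null differences of -0.05 and 0.16 from E10.5; whether these probes lie inside the deleted parts is not known, so they check nothing.

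The first comparison, triple null against MafG-intact at E10.5, asks what the loss of MafG adds where MafF and MafK are already missing. Blood and nervous system genes were lower in the triple null pool. The adult beta-globin gene Hbb-bt was 27.6-fold lower (4 probes, -4.85 to -4.72 on the log2 scale; near-identical beta-globin transcripts may share these probes), and the platelet chemokine Pf4 was 7.62-fold lower. Among neuronal genes, the log2 difference was -2.85 for the brain proteoglycan Ncan, -2.36 for the neurofilament gene Nefm, -2.21 for Nefl, -2.23 for Stmn4, -2.20 for Stmn3 and -1.90 for the RNA-binding protein gene Elavl3. The transcription factor gene Hmx1 (-2.67) and the fast muscle troponin gene Tnnc2 (-1.97) completed the 10 lowest genes at or above the median level. Among the highest genes at or above the median level were Lin28a, a repressor of let-7 maturation (7.46-fold higher), Nr6a1 at 2.12, Prtg at 2.06, Ifitm1 at 1.80, the presomitic mesoderm factor gene Tbx6 at 1.68 and the glucose transporter gene Slc2a3 at 1.54.

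The haem oxygenase gene Hmox1 (1.39), Actg2 (1.17) and Arpc3 (1.16) were also among the highest at that level; some dimmer genes named below were higher. In all, 683 of 12529 genes above background on both arrays were at least 2-fold apart, 123 higher and 560 lower in the triple null pool; with normexp background correction the count was 267, and at or above the median level 96. On one array alone, 40 genes were higher and 135 lower by a bound of at least 2-fold. The largest bounds for lower genes were those of Prim2 (at least 306-fold, from 1 probe), Mafg, Xist (141), Ppbp (46.4) and Cldn13 (21.0), and for higher genes those of Eif2s3y (203), Ddx3y (175), Kdm5d (87.3), Olfr558 (13.3) and Tex13b (11.6).

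The sexes of the pools differed along with the groups. Xist, expressed from an inactive X chromosome, was above background on the MafG-intact E10.5 array alone, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were above background on both other arrays and not on that one. Every difference from the MafG-intact E10.5 array therefore also compares pools of different sex.

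Blood genes were lower as groups. Of 23 erythroid regulator and red cell membrane genes above background on both arrays, 12 were at least 2-fold lower and none at least 2-fold higher, among them Rhd (-2.80), Kel (-1.92), Slc4a1 (-1.80) and Klf1 (-1.64); the list median was -1.23. The globins had 4 of 5 genes at least 2-fold lower, with Hba-a1 at -1.63 and the embryonic globin gene Hbb-y at -1.04, and a median of -1.06. Haem synthesis genes had a median of -0.21, with Alas2, the erythroid first enzyme, at -1.28. Megakaryocyte and platelet genes had a median of -1.96, with 8 of 14 at least 2-fold lower and the platelet glycoprotein genes Gp9 (-3.34) and Gp1ba (-2.40) among them. Macrophage and white cell genes had a median of -2.72, or -2.25 with genes at their bound, and 9 of 10 were at least 2-fold lower, with Tyrobp at -3.59 and Mpo at -2.91. Each of these 5 medians lay below at least 99.9% of 10000 random lists matched on level.

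Neuronal differentiation genes had a median of -1.39, with 25 of 38 at least 2-fold lower, including Cntn2 (-3.26) and Dcx (-2.53). Skeletal muscle genes had a median of -0.75, with 5 of 15 at least 2-fold lower, including the acetylcholine receptor gene Chrna1 (-1.72) and Mylpf (-1.54). Extracellular matrix genes had a median of -0.52, with Ogn (-2.61), Dcn (-1.60) and Lox (-1.23) at least 2-fold lower, and limb bud and cartilage genes one of -0.29, with Lhx9 at -1.34. Hepatoblast and serum protein genes had a median of -0.56, with 9 of 25 at least 2-fold lower, such as Alb (-1.98) and F2 (-1.83), and Foxa3 higher (1.07); yolk sac endoderm markers had a median of 0.11 with none 2-fold apart. These medians, the yolk sac one apart, lay below all 10000 random lists.

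Cardiac muscle genes stood on the higher side, with a median of 0.60 and 4 of 23 genes at least 2-fold higher, the contractile genes Myl7 (1.03), Myh6 (1.02) and Actc1 (1.01) and the factor gene Nkx2-5 (1.01), while Sln was lower (-2.10). Hypoxia and glycolysis genes had a median of 0.59, with Slc2a3 the 1 gene of 24 at least 2-fold apart. Early embryonic genes had a median of 0.47, and somite and tail bud genes one of 0.30, with Msgn1 (2.32), Tbx6, Nkx1-2 (1.63) and T (1.37) at least 2-fold higher. The cardiac, hypoxia and early embryonic medians lay above all 10000 random lists.

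Groups linked to small Maf partners were read next. Of 37 NRF2-linked antioxidant and detoxification genes, 3 were at least 2-fold apart, beside 5.45% of all genes, and the median was -0.07, at percentile 0.46 of 10000 random lists; Hmox1 was higher, and Me1, malic enzyme (-1.71), and Blvrb, biliverdin reductase (-1.24), were lower. The list of CNC and BACH partner genes had a median of -0.22, at percentile 1.99, and none of 6 was 2-fold apart, with Nfe2 at -0.62. The list also holds Keap1 (-0.56), which is in neither family. The large Maf gene Maf was lower (-1.21). Proteasome subunit genes had a median of 0.09, at percentile 23.5, whose sign turned with quantile normalization, and none of 38 was 2-fold apart, with Psmd13 at 0.49 and Psme3 at 0.44. None of the 27 measured members of the list of genes near Mafg was 2-fold apart (median 0.03), with Slc16a3 at 0.97 and P4hb at 0.37. The list does not cover the whole region. Fn3krp, outside it but within 100 genes of Mafg, was 4.33-fold higher, and was named after its value was seen.

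**Figure D1:**
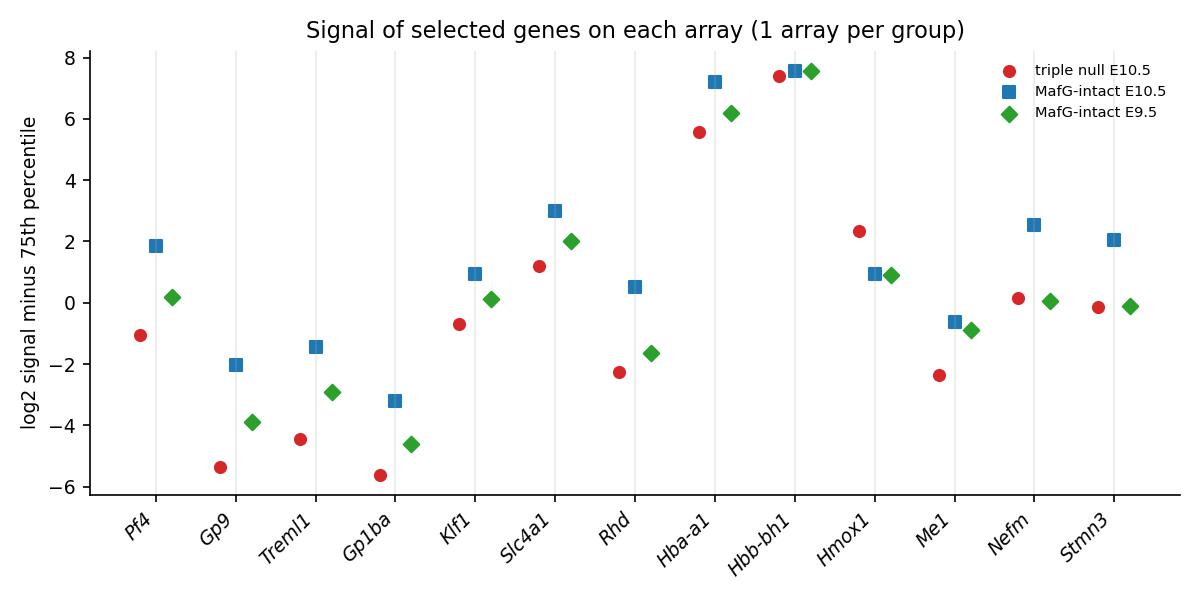
Signal (log2, minus the 75th percentile of the array) of selected genes on the triple null, MafG-intact E10.5 and MafG-intact E9.5 arrays, 1 point per array. Platelet genes (Pf4, Gp9, Treml1, Gp1ba), erythroid genes (Klf1, Slc4a1, Rhd), globins (Hba-a1, Hbb-bh1) and Me1 were lowest on the triple null array. For Hbb-bh1 the gap was small (-0.14 against E10.5 and -0.15 against E9.5). Hmox1 was highest on the triple null array, and Nefm and Stmn3 lay at about the same level on the triple null and E9.5 arrays.

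The second comparison, MafG-intact E10.5 against E9.5, measures a day of development within a genotype. Neuronal, blood and skeletal muscle genes were higher at E10.5. The log2 difference was 2.86 for Hbb-bt, 2.67 for Ncan, 2.46 for Nefm, 2.33 for Hmx1, 2.26 for Nefl, 2.19 for Stmn4, 2.18 for Stmn3, 1.88 for the somatostatin gene Sst, 1.87 for Tnnc2 and 1.86 for Id4. Lin28a (-2.50), Prtg (-2.24), Nr6a1 (-2.03), Tbx6 (-1.84), Ifitm1 (-1.71), Slc2a3 (-1.59), Ptk7 (-1.32), Prim2 (-1.27) and Aldh1a3 (-1.17) were lower. In all, 650 of 12514 genes were at least 2-fold apart, 516 higher and 134 lower at E10.5; with normexp the count was 255, and at or above the median level 92.

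Bounds of at least 2-fold were had by 128 higher and 58 lower genes, led by Xist (at least 134-fold), Ppp1r1c (23.5), Gzma (19.5), Ly86 (19.5) and Cela1 (18.3) on the higher side and by Eif2s3y (196), Ddx3y (149), Kdm5d (86.1), Gabrr2 (15.2) and Trap1a (10.7) on the lower. The neuronal median was 1.48, with 23 of 37 genes at least 2-fold higher and Cntn2 at 3.71. The macrophage median was 2.28, the platelet median 1.03 with 8 of 16 higher, the globin median 0.91, the skeletal muscle median 0.80 with 7 of 14 higher, and the erythroid median 0.74 with 8 of 24 higher; these 6 medians lay above all 10000 random lists. As in the first comparison, the pools of this pair differed in sex. Somite and tail bud genes had a median of -0.52, with Msgn1 (-2.10), Tbx6, T (-1.46) and Nkx1-2 (-1.46) at least 2-fold lower, and this median and that of hypoxia and glycolysis genes lay below all random lists.

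Markers of yolk sac endoderm were also lower at E10.5 than in the E9.5 pool, with a median of -0.41, 4 of 12 genes at least 2-fold lower and Spp2 at -2.78 and Amn at -2.58. Beside them, the hepatoblast and serum protein genes had a median of 0.20 (-0.046 with normexp), with Alb at 2.99 and Ambp at 1.29 on the higher side and Apoa1 at -1.89. The remaining medians in this comparison were 0.16 for haem synthesis, 0.26 for limb bud and cartilage (-0.026 with normexp), 0.24 for extracellular matrix, -0.26 for cardiac muscle, -0.40 for hypoxia and glycolysis, -0.40 for early embryonic genes, 0.05 for antioxidant genes (-0.040 with normexp), 0.09 for CNC and BACH partners, -0.14 for proteasome subunits and -0.09 for genes near Mafg.

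The third comparison set the triple null pool of E10.5 beside the MafG-intact pool of E9.5, to see where the triple null differed from both. Neuronal differentiation genes had a median of 0.00 in this pair, with 20 above 0 and 17 below it, and Lhx5 (2.01-fold lower) was the 1 gene of 37 at least 2-fold apart. Platelet genes were lower, with a median of -0.94 and 3 of 14 at least 2-fold lower: Treml1 (-1.51), Gp9 (-1.49) and Pf4 (-1.24). Of the 14, 11 lay below 0 and 3 just above it, namely Clec1b (0.05), Vwf (0.02) and Gp1bb (0.01). Treml1 and Gp9 were dim on the triple null array (levels of -4.43 and -5.37). The erythroid median was -0.33; it and the platelet median lay below all 10000 random lists, as did the yolk sac endoderm (-0.56) and hepatoblast (-0.23) medians. The globin median was -0.28, with Hbq1a at -1.01. Xist and the Y-linked genes did not separate these pools. The cardiac median was 0.40, with none of 23 genes 2-fold apart, the largest being Tnnt2 at 0.62; it and the skeletal muscle (0.29) and hypoxia (0.12) medians lay above all random lists. Hmox1 was higher (1.43) and Me1 lower (-1.45).

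In this pair 98 of 12521 genes were at least 2-fold apart, 32 higher and 66 lower in the triple null pool; with normexp the count was 27. By the rule for bright genes, Spr (1.49), Hmox1, Ociad1 (1.38), Taf8 (1.24) and Kifc5b (1.10) were highest, and Pf4, the yolk sac gene Rhox5 (-1.12), Lhx5, Aggf1 (-0.98) and Rbp4 (-0.94) lowest. Yolk sac endoderm markers had a median of -0.56 (0.0039 at or above the median level), with Spp2 at -3.62 and Amn at -2.04, and hepatoblast and serum protein genes one of -0.23, with Apoa1 at -3.17, Ttr at -1.71 and Alb at 1.02. The other medians were -0.15 for macrophage, 0.29 for skeletal muscle, -0.17 for somite and tail bud, -0.03 for early embryonic, 0.12 for hypoxia and glycolysis, -0.11 for limb bud, -0.06 for extracellular matrix, -0.03 for haem synthesis, -0.03 for antioxidant genes, -0.09 for CNC and BACH partners, -0.04 for proteasome subunits and -0.01 for genes near Mafg. The somite, limb bud and proteasome medians lay at percentiles 0.08, 0.09 and 0.09 of random lists, though small in size. Above the median level of detected genes, 11 genes were at least 2-fold apart, 8 of them higher.

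Against both MafG-intact arrays, 23 genes above background on all 3 arrays were at least 2-fold lower and 10 at least 2-fold higher in the triple null pool. Among the largest differences, given against E10.5 and then E9.5, were those of Tatdn2 (3.83 and 2.76), Hbb-bt (-4.79 and -1.92), the globin gene Hbq1b (-1.81 and -2.74), Nop14 (-1.63 and -2.43), Treml1 (-2.98 and -1.51), Nxph3 (2.83-fold and 3.73-fold higher), Gp9 (-3.34 and -1.49), Me1 (-1.71 and -1.45) and the gelatinase gene Mmp9 (2.86 and 1.44). The 2 probes of Nop14 disagreed: one lay at -6.22 on the triple null array and -1.36 on the E9.5 array, the other at 1.96 and 1.95, and with the brighter probe alone the differences were 0.64 and 0.0066. Prim2 is not in these counts, because its 1 probe was not above background on the triple null array (-9.24). It lay at 1.30 on the MafG-intact E10.5 array and 2.57 on the E9.5 array. Whether the transcript or the binding of the probe was lost was not tested.

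Over 12429 genes above background on all 3 arrays, the root mean square log2 difference was 0.51 between triple null and MafG-intact at E10.5, 0.50 between the MafG-intact days, and 0.24 between triple null and MafG-intact E9.5. The last was 0.484 times the first, or 0.648 times with no filter on dim probes. Of 546 genes at least 2-fold lower in the triple null pool than in the MafG-intact E10.5 pool, 422 were also at least 2-fold lower at E9.5, where independent lists would share 22.0; of 118 higher genes 72 were shared, against 1.22, and 1 gene went opposite ways. Across genes, which are not independent replicates, these differences correlated at 0.881, beside 0.410 in 100 simulated sets of unchanged arrays, and their covariance was 0.222 beside 0.00515. The simulated arrays hold spot noise and no variation between embryo pools, so the excess over them is no test of a shared effect. Both differences share the MafG-intact E10.5 array, which the independent lists leave out of account and which is 1 array and cannot be split, so part of either excess may come from it.

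**Figure D2:**
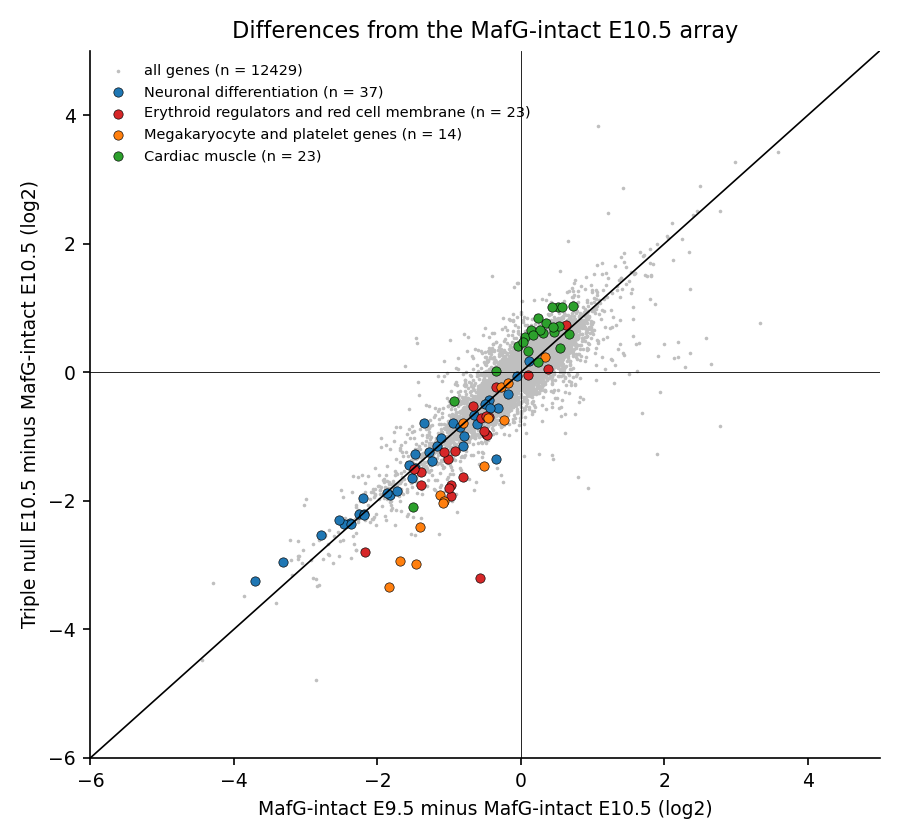
Log2 difference of the triple null array (vertical) and of the MafG-intact E9.5 array (horizontal) from the MafG-intact E10.5 array for 12429 genes, with neuronal, erythroid, platelet and cardiac genes coloured and the line of equal difference drawn. Neuronal genes lie around the line (median 0.00 between triple null and E9.5), platelet genes below it (-0.94) and cardiac genes above it (0.40); both axes share 1 array.

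**Figure D3:**
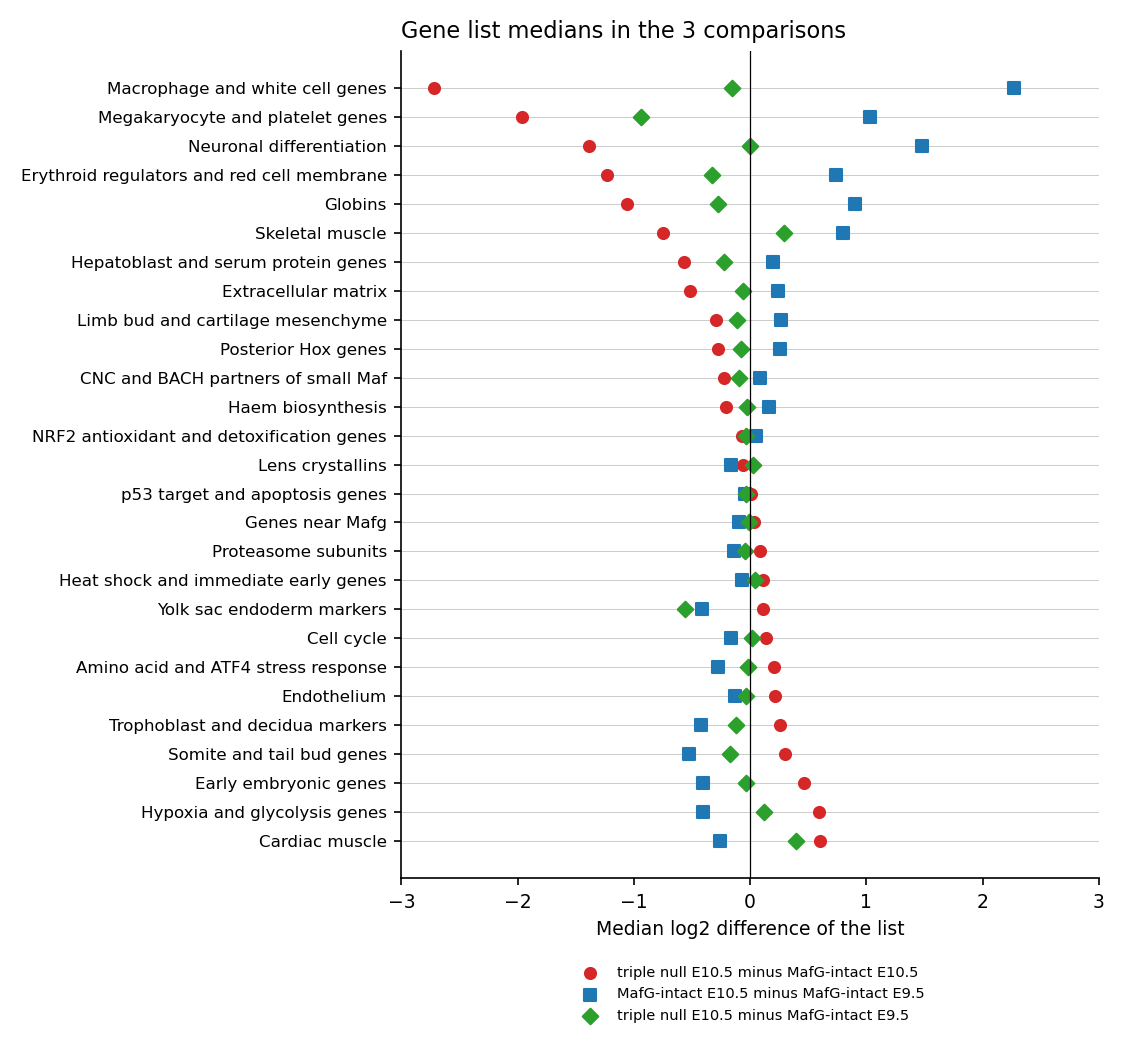
Median log2 difference of each gene list in the 3 comparisons, without the sex-linked, small Maf and large Maf lists. Circles (triple null against MafG-intact at E10.5) and squares (MafG-intact E10.5 against E9.5) lie on opposite sides of 0 for lists such as neuronal genes (-1.39 and 1.48), and diamonds (triple null against E9.5) lie nearer 0 for most of these, the platelet list (-0.94) less so.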

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

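The tests of X and Y genes, of blood content, of an age below E9.5 and of the Mafg region were chosen after the results they bear on were seen; the tests of a signal-level trend and of probe variants were set before their results.

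Among array features with no single gene symbol, which enter no comparison above, 16 were above background on the triple null array alone by at least 2-fold. The counts were 96 on the MafG-intact E10.5 array alone and 34 on the E9.5 array alone.

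The triple null array lay closer to E9.5 than to E10.5, at a ratio of root mean square differences of 0.484. Taking out the median difference in each of 20 level bins left the ratio at 0.487. This argues against a trend of the MafG-intact E10.5 array with signal level. Leaving out X and Y genes left the ratio at 0.472 over 12007 genes, so the closeness did not rest on the X and Y genes in it. The ratio took only genes above background on every array. Xist, Ddx3y, Eif2s3y, Kdm5d and Uty were therefore never in it, and leaving out X and Y genes could not test them. Younger triple null embryos, by slower development or by an earlier age at collection, stay open as untested, since no stage measure or second pool was used here. Sex effects outside X and Y, and the lone MafG-intact E10.5 array itself, also stay open.

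Platelet genes lay below even E9.5, by a median of -0.94. A stage younger than E9.5 would need a neuronal median of -1.34 if neuronal genes followed platelet genes in proportion below E9.5. The observed median was above that by 1.35, beyond the SD of 0.28 among neuronal genes, so neuronal genes did not follow in that proportion. This cannot decide on age: both medians were known when the test was set, and no array covers a stage below E9.5. A younger stage therefore stays open. Less blood in the pool stays open, because the erythroid median was above the platelet median by 0.61, within the SD of 0.91 among erythroid genes. More yolk sac tissue in the E9.5 pool also stays open: yolk sac endoderm markers were lower by a median of -0.56, with Spp2 at -3.62 and Amn at -2.04. The genotype is an untested candidate explanation, with 1 pool behind it.

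Of the 33 genes apart in the triple null pool from both other pools, 24 rested on 1 probe, such as Tatdn2, and the 2 probes of Nop14 disagreed. None of the 33 lay within 100 genes of Mafg; with bounds counted and Mafg aside, 2 of 60 (3.33%) did, beside 0.584% of all measured genes, which argues against strain DNA around Mafg as the source of most but leaves a part open, as for these 2, named after their values were seen: Fn3krp (4.33-fold higher than E10.5 and at least 23.0-fold higher than E9.5) and Tex19.1 (at least 3.62-fold and 4.99-fold lower). A strain variant under a probe could not be decided: of 7 such probes in genes with several probes, 28.6% had other probes that did not move, beside 8.06% of 62 probes apart on the MafG-intact E10.5 array alone and 71.4% of 7 on the E9.5 array alone. Only probes above background on all 3 arrays and not dim entered this count. A variant that removes the signal of a probe was therefore not covered, and Prim2, with 1 probe and no signal above background on the triple null array, could not enter. The genotype stays open as an untested biological source.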

How the results depend on the processing

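Spike-in scaling and leaving out X and Y genes were chosen after seeing the data. Counts of genes at least 2-fold apart, in the order of the 3 comparisons, were 683, 650 and 98; they became 267, 255 and 27 with normexp, whose offset shrinks differences of dim genes, 1242, 1227 and 517 with no filter on dim probes, 96, 92 and 11 at or above the median level, where fewer genes enter, 273, 242 and 28 at 3-fold and 1734, 1701 and 379 at 1.5-fold. Elsewhere they stayed within 1.5 times, and without X and Y genes they were 664, 627 and 88. No rescaling moved the share of higher genes by 10 percentage points, but filters and thresholds did: from 18.0%, 79.4% and 32.7% it went to 29.1% and 45.8% in the first and the third comparison with no filter on dim probes and to 29.8%, 68.1% and 45.6% at 1.5-fold, and in the third comparison to 17.9% at 3-fold and to 72.7% (8 higher, 3 lower) at or above the median level. The ratio of 0.484 became 0.445 with normexp, 0.648 with no filter on dim probes and 0.466 at or above the median level. Of 87 list medians, 21 were at least 0.5 from 0 (a bound also chosen after seeing the data). At or above the median level 8 were, out of fewer list medians, because lists with too few members left dropped out. Of 843 alternative list medians 813 kept their sign, and 5 changed sign after standing outside the central 95% of random lists: for E10.5 against E9.5, normexp gave -0.046 for hepatoblast, -0.026 for limb bud and -0.040 for antioxidant genes, the last also -0.024 at or above the median level, and the yolk sac median against E9.5 was 0.0039 at or above that level. Normexp moved the median of all genes to 0.11 and -0.10 in the first and second comparisons. Of 2375 alternative values of named genes at least 2-fold apart, 2268 stayed on their side at 2-fold or more and 105 kept their sign below it. The brightest probe turned Nop14 to 0.64 against E10.5 and 0.0066 against E9.5, because its probes disagree. For the other shifts the cause was not tested. No paired analysis was possible because each group had 1 array, and no array could be left out. Signal over background limits the dim genes, where spot SDs reached 0.33.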

Other observations

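Further gene groups gave smaller medians than the neuronal list in the first comparison. In triple null against MafG-intact at E10.5, the medians were 0.14 for cell cycle genes, 0.01 for p53 targets, 0.11 for heat shock and immediate early genes, 0.21 for endothelial genes, -0.06 for lens crystallins and 0.26 for trophoblast and decidua markers; none of 22 cell cycle, 19 p53 and 20 endothelial genes was 2-fold apart, and the hindbrain factor gene Egr2 was higher (1.86). Posterior Hox genes had a median of -0.27, and this median and that of the lens list turned sign with normexp; among Hox genes, Hoxc12 was at least 4.85-fold and Hoxb13 at least 2.95-fold lower. Amino acid stress genes had a median of 0.21, at percentile 98.7 of random lists, with the secreted glycoprotein gene Stc2 at 1.53.

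In MafG-intact E10.5 against E9.5, these medians were -0.17 for cell cycle, -0.05 for p53 targets, -0.07 for heat shock, -0.13 for endothelial, -0.17 for lens, -0.42 for trophoblast (percentile 1.28), 0.26 for posterior Hox (also turned in sign by normexp) and -0.28 for amino acid stress genes (percentile 0.01), 4 of 24 of them at least 2-fold lower: Trib3 (-1.65), Nupr1 (-1.14), Stc2 (-1.13) and Slc7a3 (-1.12). In triple null against MafG-intact E9.5 they were 0.01, -0.04, 0.04, -0.04, 0.03, -0.12, -0.07 and -0.02 in that order, with Hoxa13 at 1.02 and Trib3 at -1.20.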
